A study of Mus musculus with 2 samples.

How the data were processed

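Per the labels, DNase-seq was run on cerebellum of 10-day-old B6CASTF1/J male mice. DNase-seq marks accessible chromatin by the sites that the nuclease DNase I cleaves. The labels give 2 libraries as biological replicates 1 and 2 and describe the material of each as 3 males. Both libraries carry the same donor entry, so the labels do not settle how many animals the replicates share. Only the labels of replicate 2 name sequencing instruments, and they name 2 models. The libraries formed 1 group, so no contrast between groups was made, and each replicate was analysed separately.

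The authors called peaks, footprints and a per-base false discovery rate separately in each library from its filtered alignments on mm10, per the deposited text descriptions. The aligner, the callers, their versions and their thresholds are not given in the sources used here. The deposited peak lists give a signal for each peak, which is the authors' cleavage density scaled by sequencing depth. In each library the lowest distinct signal values, 997 in replicate 1 and 996 in replicate 2, were all whole multiples of a constant step, within 0.05 steps. The step was 0.00259 in replicate 1 and 0.00674 in replicate 2, a ratio of 2.60. If a step is 1 counted cleavage, replicate 1 was the deeper library by this ratio, which the files do not state. Read totals were not used here. The deposited footprint lists carry the same FDR level (p-value scale), 0.01, for every footprint and no score. The deposited per-base lists give an FDR (p-value scale) for runs of bases and hold only values under 0.05.

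Each library had a shorter and a longer peak list. Checked against the per-base values, every peak of the shorter lists held a base with an FDR under 0.001, and every peak of the longer lists held a base under 0.05. Of the longer lists' peaks, 64.8% in replicate 1 and 68.0% in replicate 2 held a base under 0.001. The shorter lists were used throughout and the longer lists as an alternative.

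Positions are 1-based on mm10 (GRCm38 p6, gene annotation GENCODE M21). Overlaps were computed with bedtools 2.31.1, sequences were read with pysam 0.24.0, and copies of a peak elsewhere in the genome were searched with blastn 2.17.0, counting alignments of at least 90% identity over at least 80% of the peak. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

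The lists of genes, the motifs, the tests and the rule for named genes were fixed before the data were examined. A promoter was the 500 bp on each side of an annotated transcription start site (TSS). The location of a peak was taken at its midpoint, as promoter, exon, intron or intergenic sequence in that order, with the TSSs of genes of any type. Shared peaks overlapped a peak of the other replicate by at least 1 bp, and 20 seeded shuffles of the peaks within their chromosomes gave the overlap of random positions. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

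For the 20 gene lists, genes with a promoter peak were compared with all other protein-coding genes by Fisher's exact test, two-sided. The locus test took the share of bases covered by peaks in the gene body with 10 kb on each side. The median of a list was set against 10000 random lists of protein-coding genes from the same deciles of gene length, two-sided. Motif matches on either strand were counted in footprints, with 5 bp on each side, that lay wholly in a peak with room for a control window. The control was 1 random window of the same width, in the same peak and outside footprints. Counts were compared by Fisher's exact test, two-sided. With the 5 bp margin this took in 522030 of 937464 footprints in replicate 1 and 320949 of 509222 in replicate 2. P-values were adjusted by the Benjamini-Hochberg method over the 20 lists or the 26 motifs. A list or motif was called only with an adjusted p under 0.05 in both replicates and in the same direction. Log2 ratios and odds ratios had 0.5 added to each count. A count of 0 was read as allowing up to 3 counts. Ratios of locus coverage between the replicates had 0.1 added to each percent. Their 95% intervals come from 2000 bootstrap draws over the genes of a list, those of the shares of peaks in forebrain and Hox loci from as many over loci, and that of footprints per peak from 200 over peaks. None of these intervals covers the spread between libraries.

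Tested on simulated data, the promoter test called 244 of 250 lists with a lowered share and 0 of 750 lists drawn like the rest. Promoter peaks were drawn independently for each simulated replicate. In the real data 69.1% and 66.2% of genes had one in replicates 1 and 2, and 65.8% in both. The 0 of 750 therefore does not give the rate of false calls for replicates this alike. The locus test called 46 of 50 lists raised 4-fold and 0 of 150 others. The motif test called 13 of 13 planted motifs and 0 of 26 with none planted. Its simulated windows drew all bases equally, whereas real footprint windows were richer in GC than control windows (56.9% against 52.8% in replicate 1). The simulation therefore does not cover calls that arise from GC content. Overlap counts and covered bases matched a direct count at 400 of 400 intervals each.

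Named genes were the 2 members of each list with the highest share of the locus in peaks (mean of the replicates), and up to 3 members without a promoter peak in either replicate of each list of cerebellar cells. Added to these were the 10 loci with the highest share among those with at least 5 peaks in each replicate, the 10 strongest shared autosomal peaks, and the 5 strongest peaks of each replicate without a peak in the other. Some genes that the rule picked are not reported. Genes named outside the rule were chosen after their values were seen.

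The alternatives were a 50% reciprocal overlap, the stronger 50% of the peaks, equal numbers of peaks, the longer lists, promoter windows of 100 and 2000 bp, and locus flanks of 50 kb or none. Others left out promoter peaks, the footprint margin, footprints within 2000 bp of a TSS or each replicate in turn, took the reversed consensus as the control, or used FDR thresholds of 0.01 and 0.001. Equal numbers of peaks in the locus test, the gene families, the grouping of Hox genes by cluster, the ranking of loci by their difference between replicates and the test of forebrain genes for a brainstem source were chosen after seeing the data. The erythroid gene Ahsp had no locus in the annotation used and was left out. Allele-specific accessibility was not analysed here.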

Results

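Accessible chromatin was measured by DNase-seq in cerebellum of 10-day-old male B6CASTF1/J mice, a cross of the C57BL/6J and CAST strains. The data held 1 group with 2 biological replicates. Replicate 1 had 199947 peaks over 40.7 Mb and replicate 2 had 143313 peaks over 25.6 Mb. The median peak width was 180 bp in both. Broad peaks of over 500 bp made up 2.81% of the peaks of replicate 1 and 0.431% of those of replicate 2. The median peak signal, in the authors' depth-scaled units, was 0.559 in replicate 1 and 1.24 in replicate 2. With n = 2, each SD below rests on 2 values, and differences between the replicates could not be tested.

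Of the 10 strongest autosomal peaks found in both replicates, 7 were centred within 270 bp of a TSS of a protein-coding gene. By the mean signal of the replicates, the strongest was at Dynlt1b, which encodes a dynein light chain, on chromosome 17 from 6430021 to 6430180. Its signals were 25.8 in replicate 1 and 77.3 in replicate 2. This sequence had 3 other near-identical copies in the genome. The next was at the promoter of Hjurp, which encodes a chaperone of the centromeric histone CENP-A, on chromosome 1 from 88277521 to 88277760, with signals of 29.0 and 63.8. In replicate 1 the peaks of Hjurp and Nup107 (27.7) were stronger than that of Dynlt1b. Bahcc1 on chromosome 11, Sugct on chromosome 13, Nup107 and Amd1 on chromosome 10, and Ankhd1 on chromosome 18 had the other promoter peaks. The remaining 3 lay farther from such a TSS. The nearest were those of Cct8l1, Lemd2 and Gm31371, at 13684, 36262 and 218831 bp, and the last sequence had 5 other copies. Whether a TSS of another type of gene lay closer was not examined.

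Replicate 1 shared 64.4% of its peaks with replicate 2 (95% interval 64.2 to 64.6), and replicate 2 shared 89.99% with replicate 1 (89.8 to 90.2). Shuffled peaks shared 2.14% and 2.91% on average over 20 shuffles. The peaks without a counterpart numbered 71155 in replicate 1 and 14344 in replicate 2. Of these, 48.7% and 89.2% held a base with an FDR under 0.05 in the other replicate. They were weaker than shared peaks, with median signals of 0.303 against 0.903 in replicate 1 and 0.539 against 1.40 in replicate 2. The strongest peak found in replicate 2 alone was next to Rab40c, which encodes a small GTPase, with a signal of 29.8, and others were near Ap3d1 and Wdr25. In replicate 1 they included peaks near Gm21887 on chromosome X, Sesn3, Myh9 and Dcaf11. Each of these positions held a base with an FDR of 5.1e-76 or lower in the other replicate.

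Across 132322 pairs of overlapping peaks, the signals of the replicates had a Spearman's rho of 0.893 and a Pearson's r of 0.908 on the log2 scale. These were computed across peaks, which are not independent replicates. The signal of replicate 2 was higher by a median of 0.72 on the log2 scale (1.64-fold), with an SD of 0.64 across pairs. The ratio was lowest among peaks poor in GC, with a median log2 ratio of 0.13 in the decile with a median GC content of 43.8%. It was 0.88 in the decile at 59.0%, and 0.85 and 0.80 in the deciles richest in GC, at 63.2% and 70.96%.

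**Figure D1:**
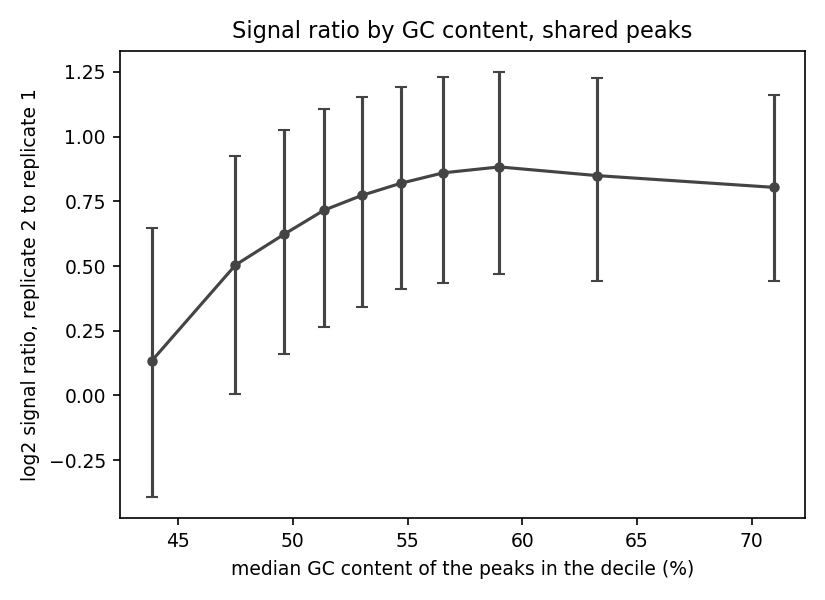
Median log2 ratio of the peak signal, replicate 2 to replicate 1, in deciles of the GC content (percent) of shared peaks; bars span the quartiles across peaks. The median is 0.13 in the decile poorest in GC, 0.88 at 59.0% GC and 0.80 in the decile richest in GC.

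Promoters were the class of sequence with the most peaks for its length. They held 16.9% of the peaks of replicate 1 and 19.8% of those of replicate 2 (mean 18.3% ± 2.02, SD, n = 2), against 3.16% of the bases of the genome. Exons held 6.85% ± 0.357 of the peaks and 3.56% of bases. Introns held 40.7% ± 0.850 of the peaks and 38.8% of bases, and intergenic sequence held 34.1% ± 0.809 of the peaks and 54.5% of bases. Chromosome X had 29.9 and 20.8 peaks per Mb in replicates 1 and 2, against 79.1 and 56.7 per Mb of autosome. Its median peak signal was 0.342 and 0.701, against 0.564 and 1.25 on the autosomes. Males carry a single copy of it. Chromosome Y had 93 and 38 peaks.

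Which cell types' genes had open promoters was examined with 20 lists of marker genes. Of 21938 protein-coding genes, 69.1% had a promoter peak in replicate 1, 66.2% in replicate 2 and 65.8% in both. All 14 housekeeping genes, such as Actb (cytoplasmic actin) and Rpl13a (a ribosomal protein), had one in both replicates. With this window of 500 bp the promoters of liver genes were the least open, with 1 of 13 in each replicate, which was Ahsg in replicate 1 and Tat in replicate 2. Fewer genes than elsewhere also had a promoter peak among the microglial (3 of 12), muscle (3 of 12), germ cell (3 of 12) and lymphocyte lists (4 of 12), each with the same count in both replicates. The microglial genes C1qa and C1qb (subunits of complement C1q) and Cx3cr1 (the fractalkine receptor) had none.

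By Fisher's exact test, two-sided, these 6 lists passed in both replicates. The adjusted p was 0.0312 and 0.0142 for housekeeping genes, 0.000139 and 0.000197 for liver, and 0.0106 and 0.0142 for each of microglia, muscle and germ cells. It was 0.0382 and 0.0458 for lymphocytes. With the longer peak lists none of the 20 lists was called, the directions of these 6 being the same. With a promoter window of 2000 bp the housekeeping and muscle lists were not called, and with the stronger 50% of the peaks the lymphocyte list was not. Liver genes were not the lowest with the window of 2000 bp, at 30.8% against 25% of microglial genes in each replicate. Nor were they in replicate 1 with the longer peak list, at 46.2% against 41.7% of germ cell genes. Genes are not independent replicates.

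All 12 granule neuron genes, all 12 granule progenitor genes, all 6 unipolar brush cell genes and all 10 immediate early genes had a promoter peak in both replicates. The granule lists reached adjusted p = 0.0518 in replicate 1 and 0.0227 in replicate 2 by Fisher's exact test, so they were not called. The immediate early list reached 0.0748 and 0.0362, and the unipolar brush cell list 0.233 and 0.147. These 4 lists were at their full count, so no higher share was possible. With this window, lists of these sizes could hardly be called higher in replicate 1, and the missing calls say little about them. With a promoter window of 100 bp or the stronger 50% of the peaks both granule lists were called higher, and with the stronger 50% the immediate early list was too. Among Bergmann glia and astrocyte genes 11 and 12 of 12 had a promoter peak in replicates 1 and 2 (adjusted p = 0.172 and 0.0227 by Fisher's exact test), and among GABAergic interneuron genes 12 and 10 of 12. Among Purkinje cell genes the counts were 11 and 8 of 12. Pcp2, a classical Purkinje cell marker, had no promoter peak in either replicate. In the oligodendrocyte lineage 8 and 7 of 12 genes had one. The myelin genes Mag and Mog had none, while Olig2, which specifies the lineage, had one in both. The counts were 7 and 5 of 12 for endothelium and mural cells, 6 and 4 of 10 for choroid plexus and ependyma, and 4 and 2 of 9 for erythroid cells. They were 9 and 8 of 11 for mid-hindbrain patterning genes, 12 and 8 of 13 for forebrain genes, and 8 and 2 of 17 for Hox genes. None of these lists passed in both replicates. The erythroid list in replicate 2 had adjusted p = 0.0227 and the Hox list 0.000108 by Fisher's exact test, against 0.195 and 0.117 in replicate 1. The Hox list was called lower with a promoter window of 100 bp, and the Hox, erythroid and endothelial lists were with the stronger 50% of the peaks.

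**Figure D2:**
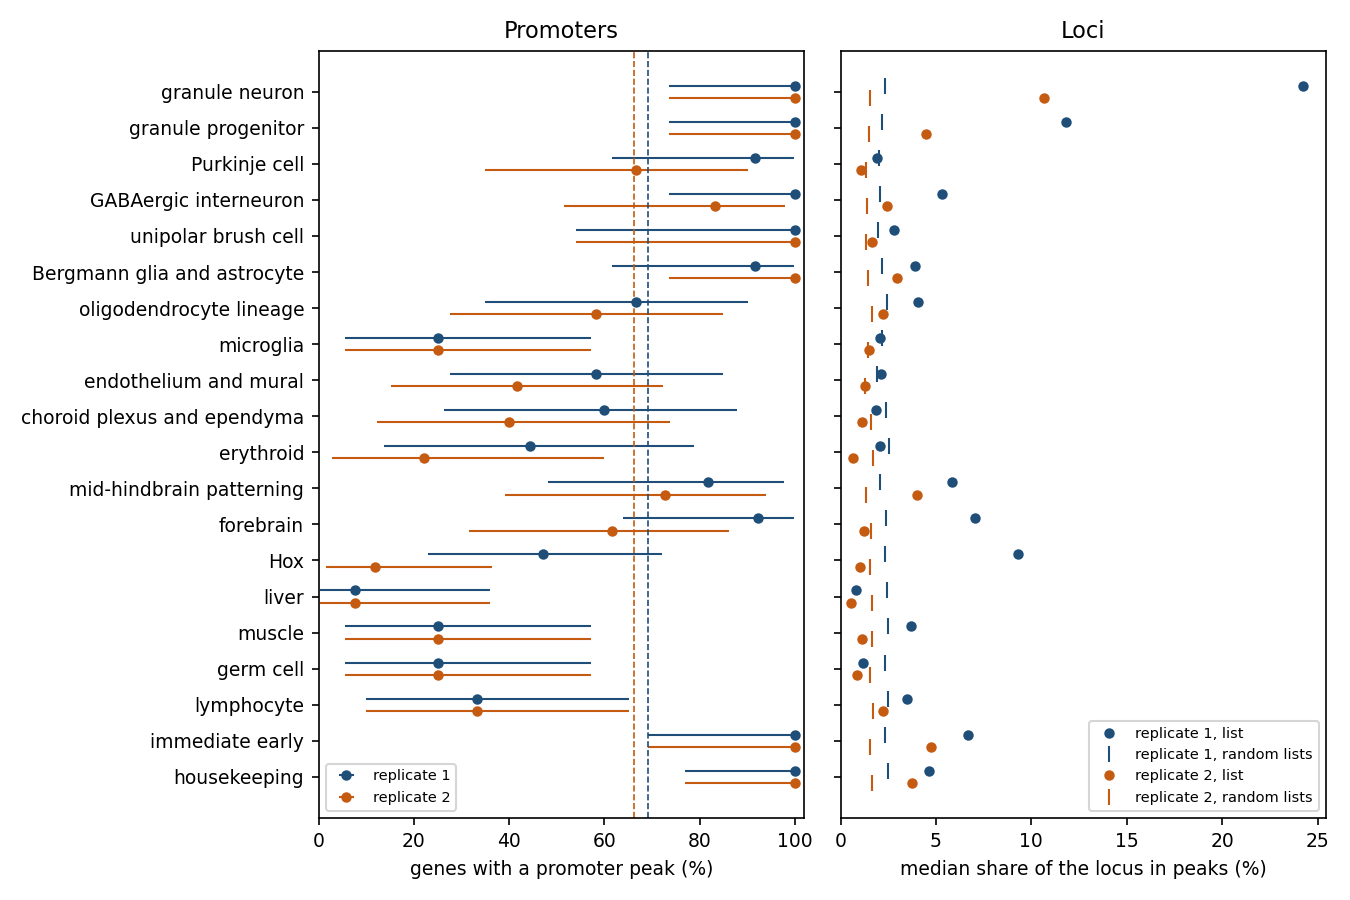
Left, the percent of each list's genes with a promoter peak in each replicate (points) with exact 95% intervals, and dashed lines at 69.1% and 66.2%, the shares of all protein-coding genes in replicates 1 and 2. Right, the median percent of the locus covered by peaks (points) beside the mean of random lists matched on gene length (ticks); granule neuron genes lie at 24.3% and 10.7%.

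With flanks of 10 kb, granule neuron loci were the most densely covered by peaks of the 20 lists in both replicates. With flanks of 50 kb the Hox list had a higher median in replicate 1, at 11.9% against 9.44%. With 10 kb the median granule neuron gene had 24.3% of its locus in peaks in replicate 1 and 10.7% in replicate 2, against 2.35% and 1.57% for random genes of like length. Granule progenitor loci had 11.8% and 4.46%, immediate early loci 6.69% and 4.73%, and mid-hindbrain patterning loci 5.86% and 4.02%. These 4 lists were called higher, and no list was called lower. The adjusted permutation p was 0.00133 in replicate 1 and 0.00200 in replicate 2 for both granule lists, where the raw p of 0.0002 is the smallest that the random lists can give. It was 0.0187 and 0.0110 for mid-hindbrain patterning and 0.0269 and 0.00400 for immediate early genes. Mid-hindbrain patterning was not called with flanks of 50 kb, with the gene body alone or with the stronger 50% of the peaks, and immediate early genes were not called with flanks of 50 kb.

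In the granule neuron list Zic1, a zinc finger factor of granule neurons and their progenitors, on chromosome 9 from 91358058 to 91365810, had 35.1% ± 26.4 (SD, n = 2) of its locus in peaks, 53.7% in replicate 1 and 16.4% in replicate 2. Zic2 on chromosome 14 had 32.9% ± 25.2. Among granule progenitor genes Ccnd1, a cyclin of the G1 phase, had 16.7% ± 13.1 and Barhl1, a homeobox factor, had 15.5% ± 15.9. Among mid-hindbrain genes Barhl2 had 28.0% ± 19.2 and En2, an engrailed homeobox factor, had 17.5% ± 10.9. Egr1 and Junb, transcription factors induced by neuronal activity, had 13.5% ± 9.27 and 13.2% ± 3.68. The strongest promoter peak of Egr1 had a higher signal than 99.7% of all peaks in replicate 1 and 98.5% in replicate 2.

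Loci with at least 5 peaks in each replicate, 9699 in number, were ranked by the mean of the replicates. The most covered was that of the homeobox gene Uncx on chromosome 5 (139543494 to 139548179), at 36.2% ± 20.6 (SD, n = 2). Zic1, Zic5, Zic2, Neurod2, Zic4, Barhl2, Lyl1, Pax6 and Skida1 followed, from 35.1% to 26.1%. Uncx led in neither replicate: Zic1 was higher in replicate 1 (53.7% against 50.8%) and Neurod2 in replicate 2 (25.2% against 21.65%). Neurod2, a basic helix-loop-helix factor of neurons, had 37.9% and 25.2% in replicates 1 and 2. Pax6, a paired-box factor of the granule lineage, had 36.1% and 16.7%. The neighbouring loci of Zic1 and Zic4, and of Zic2 and Zic5, share bases within the 10 kb flanks.

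**Figure D3:**
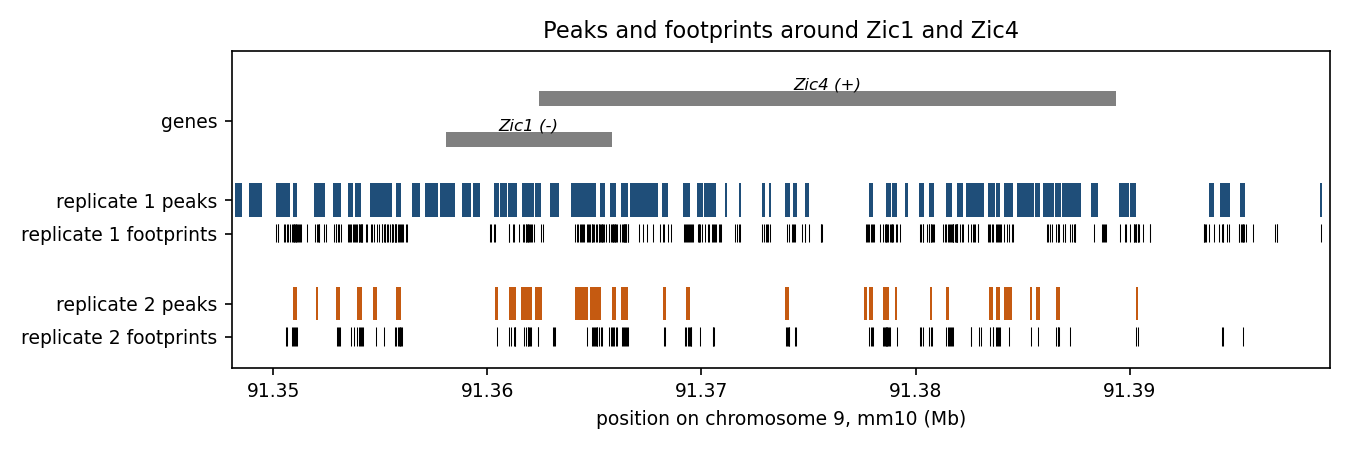
Peaks (bars) and footprints (lines at their centres, not to width) of both replicates around Zic1 and Zic4 on chromosome 9 of mm10, with position in Mb on the x axis and gene bodies in grey. Replicate 1 had 45 peaks in the Zic1 locus and replicate 2 had 19.

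For the other cell types of the cerebellum no list was called. In the Purkinje cell list, with medians of 1.91% and 1.09%, the LIM homeobox genes Lhx5 and Lhx1 had 15.1% ± 19.8 and 14.5% ± 9.15. Lhx5 had 29.1% in replicate 1 and 1.15% in replicate 2. In the GABAergic interneuron list, with 5.34% and 2.44%, Tfap2b had 10.96% in replicate 1 and 0.256% in replicate 2. In the unipolar brush cell list, with 2.80% and 1.66%, Eomes had 7.84% ± 1.89 and Calb2 had 4.97% ± 1.01. In the Bergmann glia and astrocyte list, with 3.89% and 2.94%, Sox9 had 11.2% ± 3.93 and Hes5 had 9.34% ± 3.83. In the oligodendrocyte list, with 4.05% and 2.25%, Olig2 had 19.5% ± 16.5 and Nkx2-2 had 21.9% in replicate 1 and 1.35% in replicate 2. GABAergic interneuron genes passed in replicate 1 (adjusted permutation p = 0.00400) and not in replicate 2 (0.0811). With promoter peaks left out this list was called higher (adjusted permutation p = 0.00900 and 0.0192).

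Among lists of other cells, the microglial list had medians of 2.09% and 1.48%, with Aif1 at 4.94% ± 3.10 and Cx3cr1 at 3.99% ± 2.57. The endothelial and mural list had 2.11% and 1.29%, with Sox17 at 7.67% ± 10.9 and Cdh5 at 2.59% ± 0.309. Sox17 had 15.3% in replicate 1 and 0% in replicate 2. The choroid plexus and ependymal list had 1.84% and 1.11%, with Otx2, which granule progenitors of the posterior cerebellum also express, at 16.4% ± 15.0 and Foxj1 at 6.03% ± 0.839. The erythroid list had 2.06% and 0.668%, with Tal1 at 7.25% ± 4.89 and Epor at 4.71% ± 3.46. The liver list had 0.807% and 0.533%, with Tat at 3.98% ± 0.168 and Fgb at 2.69% ± 0.761. The muscle list had 3.71% and 1.12%, with Des at 7.03% ± 5.13 and Acta1 at 5.33% ± 1.35. The germ cell list had 1.20% and 0.845%, with Prm2 at 5.05% ± 0.0571 and Stra8 at 2.56% ± 1.25. The lymphocyte list had 3.49% and 2.23%, with Cd4 at 7.08% ± 3.18 and Cd79a at 4.52% ± 0.174. The housekeeping list had 4.64% and 3.73%, with Rpl13a at 13.2% ± 13.4 and Actb at 8.68% ± 3.19, and passed in replicate 2 (adjusted permutation p = 0.0184) and not in replicate 1 (0.0947). With the stronger 50% of the peaks the housekeeping list was called higher (adjusted permutation p = 0.0493 and 0.00200).

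As a ratio of replicate 1 to replicate 2 relative to all genes, locus coverage differed most in the forebrain and Hox lists, with median log2 ratios of 2.40 (95% interval 0.50 to 4.37) and 1.65 (-0.22 to 3.55). These intervals resample the genes of a list and leave out the spread between libraries, so they are no test of the difference between the replicates. Smaller ratios, with intervals above 0 of this kind, were those of mid-hindbrain patterning, 0.90 (0.23 to 1.33), granule neurons, 0.78 (0.27 to 1.20), granule progenitors, 0.36 (0.00074 to 1.41), choroid plexus and ependyma, 0.35 (0.066 to 1.18) and Purkinje cells, 0.32 (0.015 to 0.87). With equal numbers of peaks the ratio was 0.21 for choroid plexus and ependyma and 0.088 for Purkinje cells. Dlx1, a homeobox factor of forebrain interneurons, on chromosome 2 from 71528113 to 71533981, had 47.9% of its locus in peaks in replicate 1 and 0.649% in replicate 2. Hoxa2 had 41.1% and 2.54%. Both lists passed in replicate 1, with medians of 7.05% for forebrain genes (adjusted permutation p = 0.00640) and 9.32% for Hox genes (0.00133). Neither passed in replicate 2, with 1.22% and 1.01% (0.663 and 0.589). In replicate 1 the Hox list no longer passed with the gene body alone (adjusted permutation p = 0.499), the stronger 50% of the peaks (0.434) or equal numbers of peaks (0.427), the last chosen after seeing the data. With the gene body alone the Hox median in replicate 1 was 0%, below the 1.88% of random lists. The forebrain list no longer passed with flanks of 50 kb (0.261) or the stronger 50% of the peaks (0.122). Replicate 1 peaks in these loci held a base with an FDR under 0.05 in replicate 2 in 33.8% of cases, against 75.2% of other peaks matched on signal.

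**Figure D4:**
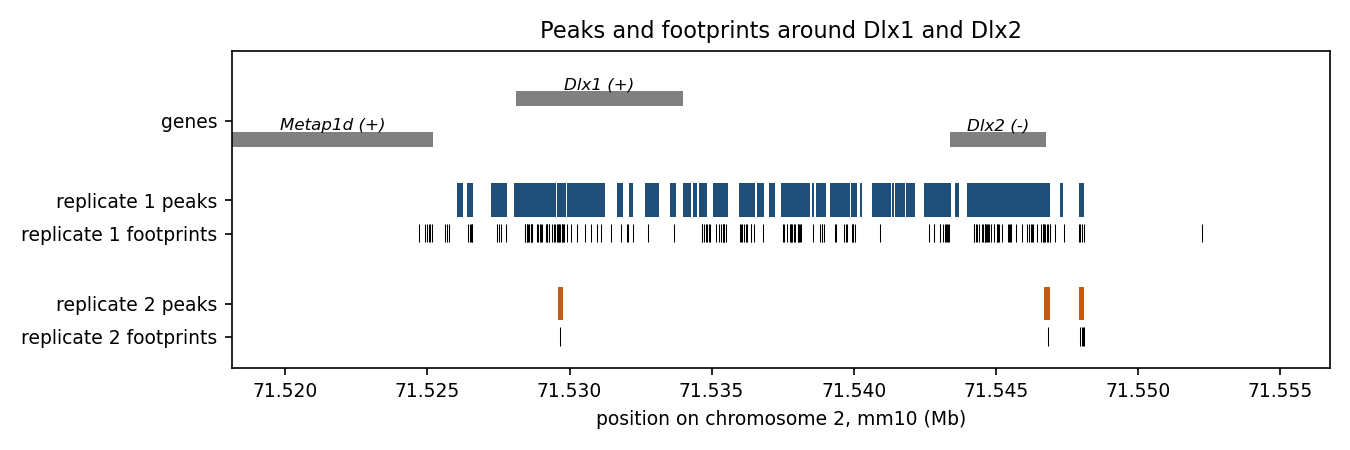
Peaks (bars) and footprints (lines at their centres, not to width) of both replicates around Dlx1 and Dlx2 on chromosome 2 of mm10, with position in Mb on the x axis and gene bodies in grey. Replicate 1 had 40 peaks in the Dlx1 locus and replicate 2 had 1.

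Footprints, short stretches inside accessible chromatin that a bound protein shields from DNase I, numbered 937464 in replicate 1 and 509222 in replicate 2. Their median width was 11 bp in both, and 66.65% and 74.5% of them overlapped a peak. The Zic1 locus held 210 and 93 of them, the Uncx locus 226 and 114, and the Dlx1 locus 130 and 1. A footprint lay in 88.8% of the peaks of replicate 1 and in 89.3% of those of replicate 2, with means of 3.19 and 2.66 per peak. Replicate 1 shared 38.8% of its footprints with replicate 2 (95% interval 38.7 to 38.9), and replicate 2 shared 73.1% (73.0 to 73.2). Within shared peaks 59.7% and 79.1% were shared, against 44.2% and 57.8% for footprints shuffled within these peaks.

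Among the strongest peaks, the promoter peak of Dynlt1b held a footprint with an SP/KLF match and another with an NRF1 match in both replicates. Nup107 had footprints with NRF1 and SP/KLF matches, Bahcc1 with an NFY match, Sugct with SP/KLF matches and Ankhd1 with an ETS match in both. The peak nearest to Cct8l1 held footprints with NFY and SP/KLF matches in both. That nearest to Gm31371 held a footprint with a CTCF match in both replicates, from 20122177 to 20122221 on chromosome 8 in replicate 1. No footprint at Hjurp, Amd1 or Lemd2 held a match of the 26 motifs.

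The motifs of CTCF, ZIC, ATOH1, NEUROD1 and NFI were among those more frequent in footprints than in windows of the same width elsewhere in the same peaks. CTCF, an insulator protein, matched in 0.544% of the footprint windows of replicate 1 and 1.06% of those of replicate 2, against 0.00690% and 0.0106% of control windows, a log2 ratio of 6.45 ± 0.24 (SD, n = 2). The ZIC motif had a log2 ratio of 3.64 ± 0.21, and the E-boxes of ATOH1 and NEUROD1, basic helix-loop-helix factors of granule progenitors and neurons, had 1.70 ± 0.27 and 1.66 ± 0.31. The full palindromic site of NFI, a family active in granule neurons, matched in 429 and 177 windows and in 0 of 522030 and 0 of 320949 control windows. A count of 0 allows up to 0.000575% and 0.000935% of control windows, so the site was at least 143-fold and 59-fold more frequent.

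The log2 ratio was 3.67 ± 0.51 for CRE, 3.38 ± 0.17 for SP/KLF, 3.23 ± 0.07 for EBF, 3.03 ± 0.24 for the X-box of RFX and 2.70 ± 0.25 for NRF1. YY1 had 1.23 ± 0.07, GLI, the effector of Sonic hedgehog signalling, 0.86 ± 0.14, ETS 0.46 ± 0.04 and NFY 0.14 ± 0.06. In all, 14 of the 26 motifs were called more frequent by Fisher's exact test, two-sided, and 8 less frequent. The windows numbered 522030 and 320949 and are not independent replicates.

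The sizes of these ratios moved with the control. Reversing a consensus keeps its base composition but changes which bases adjoin. The SP/KLF consensus reads the same in reverse, so this control covered the 25 other motifs. The SP/KLF ratio thus had no control of like base composition, and footprint windows were richer in GC than control windows. The reversed CTCF and NEUROD1 words gain a CG pair, the reversed YY1 word gains a further pair, and the reversed CRE word loses its pair. The reversed ZIC word always holds a CG pair, which the motif holds only in some forms. The reversed ATOH1 word holds such a pair in some forms and the motif in none. How common each reversed word is outside footprints was not measured, so ratios against it also carry that difference. When the reversed consensus in the same footprints was the control, the mean log2 ratio was lower for EBF (1.01), CRE had 1.87 and 2.05 in replicates 1 and 2, and GLI turned to -0.58. It was higher for NFY (2.87), ZIC (4.58), RFX (4.59), ATOH1 (5.27), NEUROD1 (7.48) and CTCF (9.43), and the reversed consensus of YY1 matched in 0 windows of either replicate, against 200 and 153 for the motif. Over 2000 bp from a TSS, ETS had ratios of 0.39 and 0.31 in replicates 1 and 2 with 72 and 51 matches, against 0.43 and 0.49 with 636 and 582 matches in all footprint windows, and was not called. YY1 had a mean of 2.14 there. Without the margin around footprints NFY (0.18 and 0.14), YY1 (1.07 and 0.58) and GLI (0.42 and 2.13) were not called, and the mean ratio was 9.01 for CTCF, 5.13 for ZIC, 5.03 for CRE, 4.40 for EBF, 4.39 for SP/KLF, 4.10 for RFX and 3.74 for NRF1.

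The motifs called less frequent were those of AP-1, MEF2, SOX, POU/octamer, homeodomain, ROR, PU.1 and GATA factors. The GATA motif had a log2 ratio of -1.21 ± 0.17, that of PU.1, a factor of microglia and other myeloid cells, -0.81 ± 0.10, that of MEF2, a family active in neurons and muscle, -0.73 ± 0.37, and that of AP-1 -0.59 ± 0.05. Against their reversed consensus 6 of these 8 had a ratio above 0 in both replicates, with means from 0.25 for PU.1 to 4.92 for POU/octamer. The reversed POU/octamer consensus holds a CG pair that the motif lacks, so the size of its ratio also carries that difference. SOX had 0.18 and -0.11 in replicates 1 and 2, and GATA had -0.18 and 0.0077. GATA, SOX and PU.1 were then not called. Footprint windows had a mean GC content of 56.9% and 58.8%, and control windows 52.8% and 54.1%. REST, the repressor of neuronal genes, passed in replicate 1 (log2 ratio 1.47) and not in replicate 2 (0.86, adjusted p = 0.0552 by Fisher's exact test). TEAD, HNF1 and HNF4 were not called. Against the reversed consensus REST, TEAD and HNF4 were called more frequent, and without the margin TEAD was called less frequent.

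**Figure D5:**
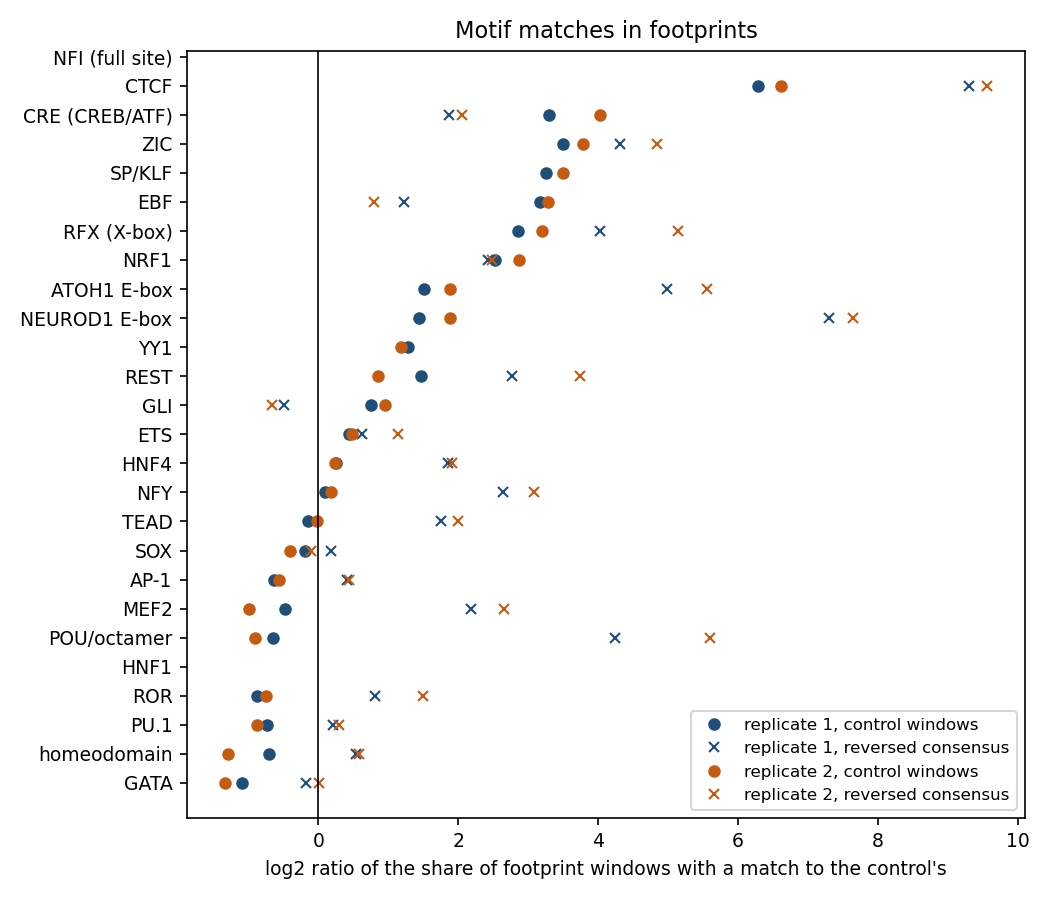
Log2 ratio of the share of footprint windows with a motif match to that of control windows (circles), and to that of the reversed consensus in the same footprint windows (crosses), in each replicate; ratios with a count of 0 are not drawn. SP/KLF has no crosses, because its consensus reads the same in reverse. CTCF lies at 6.28 and 6.62 against control windows, and POU/octamer, AP-1 and MEF2 lie on opposite sides of 0 under the 2 controls.

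At single bases, 109.1 Mb of replicate 1 and 66.1 Mb of replicate 2 had an FDR under 0.05. Of these bases 37.3% and 38.8% lay in peaks, and of those under 0.001, 58.0% and 58.2%.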

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

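Of the alternatives, the locus test with equal numbers of peaks was chosen after the result was seen. No paired analysis was possible because the 2 libraries formed 1 group with no contrast, and the footprints could not be restricted to the stronger 50%, because each carried the same FDR level. The cause of the changes that follow was not tested, except where a smaller set of peaks or a wider window sets the value by construction. With a 50% reciprocal overlap, 56.7% and 79.0% of the peaks of replicates 1 and 2 were shared, 28.2% and 52.0% of the footprints, and rho of the signals was 0.895. With the stronger 50% of the peaks, 68.8% and 95.6% were shared, rho was 0.820 and 26.6% of the peaks lay at promoters. With the same number of peaks in each replicate 79.3% and 79.6% were shared, and with the longer peak list 59.2% and 86.9%. Promoter windows of 100 and 2000 bp held 9.52% and 31.4% of the peaks, and left 3 and 0 lists with more promoter peaks than other genes, against 1 in the report, and 6 and 4 with fewer, against 5. With 100 bp both granule lists were called higher and the Hox list lower. With 2000 bp the housekeeping (log2 odds ratio 3.49) and muscle lists (-1.15) were no longer called. With the stronger 50% of the peaks 4 lists had more promoter peaks, both granule lists among them, and 7 had fewer, the Hox list among them, while the lymphocyte list (-2.14) was no longer called. With the longer peak list 0 lists had more and 0 had fewer promoter peaks, with log2 odds ratios of -1.76 for microglia, -2.94 for liver, -1.53 for muscle, -1.99 for germ cells, -1.75 for lymphocytes and 3.56 for housekeeping genes. From single replicates 1 to 5 lists had more promoter peaks and 5 to 7 lists had higher locus coverage. The GABAergic interneuron list was called higher with promoter peaks left out, and the housekeeping list with the stronger 50% of the peaks. With locus flanks of 50 kb 2 lists had higher coverage. The mid-hindbrain patterning list was then 1.23 percentage points above random lists and the immediate early list 2.18, and neither was called. The mid-hindbrain patterning list was also not called with the gene body alone (2.70 points) or the stronger 50% of the peaks (2.79 points). Both granule lists were called higher with flanks of 50 kb, with the gene body alone, without promoter peaks, with the stronger 50% of the peaks, with equal numbers of peaks and in each replicate by itself. With the reversed consensus as control 1 motif was less frequent, and the log2 ratio turned to 0.43 for AP-1, 2.42 for MEF2, a mean of 0.036 for SOX (0.18 and -0.11 in replicates 1 and 2), 4.92 for POU/octamer, 0.56 for homeodomain, 1.16 for ROR, 1.88 for TEAD, 0.25 for PU.1 and -0.58 for GLI. Under FDR thresholds of 0.01 and 0.001, replicate 1 had 87.2 and 69.2 Mb and replicate 2 had 53.9 and 43.8 Mb. Of the values for promoter lists 96 of 120 kept their call, of those for locus lists 130 of 140 and of those for motifs 110 of 129. A list or motif called neither in the report nor under the alternative counted as kept, and its direction was not compared. Of the 57 other values and counts 28 moved. Of 47 named loci, 18 moved by over 1 SD with flanks of 50 kb, 26 with the gene body alone, 13 without promoter peaks and 8 with the stronger 50% of the peaks. The read depth was not known, so a peak missing from a list is not shown to be absent, and 48.7% of the peaks of replicate 1 without a counterpart had a base under an FDR of 0.05 in replicate 2.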

Other observations

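The gene families, the grouping of Hox genes by cluster, the ranking of loci by their difference between replicates and the test of forebrain genes for a brainstem source were chosen after the result was seen. These families were not tested against other genes, of which 69.1% and 66.2% had a promoter peak in replicates 1 and 2. Among glutamate receptor subunits 28 and 26 of 28 genes had one, among subunits of voltage-gated calcium channels 24 and 23 of 26, among potassium channels 79 and 74 of 94, and among GABA-A receptor subunits 16 and 15 of 19. Of the ribosomal protein genes 92, or 91.1%, had one in each replicate (exact 95% interval 83.8 to 95.8). So did 346 and 343 of 394 zinc finger genes named Zfp and 59 and 57 of 67 replication-dependent histone genes. Of 1135 olfactory receptor genes 55 and 39 had a promoter peak (4.85% and 3.44%), of 329 vomeronasal receptor genes 6 and 3, of 64 defensin genes 4 and 2, and of 53 keratin genes 15 and 11. The protocadherin clusters, whose promoters are chosen cell by cell in neurons, had a promoter peak at 43 of 57 genes in replicate 1 (75.4%, 62.2 to 85.9) and 16 of 57 in replicate 2 (28.1%, 16.97 to 41.5).

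Most loci had more of their length in peaks in replicate 1, with medians of 2.13% and 1.46% over 21938 genes. The 20 loci with the highest differences included Sp8 (49.1% and 0.686% in replicates 1 and 2), Evx1 (46.0% and 0.723%), Hand2, a factor of heart and limb (42.9% and 0.592%), and Zic1 (53.7% and 16.4%). In the Hoxa cluster 10 of 11 genes were covered over 5 times more in replicate 1, in Hoxb 2 of 10, in Hoxc 0 of 9 and in Hoxd 3 of 9. Posterior members were among them, such as Hoxa13 (32.5% and 1.45%) and Hoxd13 (15.4% and 2.15%). In the other direction the highest difference was 5.14 points, at Emilin3 (1.56% and 6.69%).

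Forebrain loci, some Hox loci and, by smaller ratios, those of mid-hindbrain patterning (0.90, 0.23 to 1.33) and of granule neurons (0.78, 0.27 to 1.20) among other lists had a larger share of bases in peaks in replicate 1 relative to other genes (median log2 ratios with 95% intervals over genes), and no biological difference could be tested because the design holds 1 group. Greater depth of replicate 1 and the GC content of the peaks were examined as the whole cause at the forebrain and Hox loci alone. Of 408 replicate 1 peaks in the 21 merged loci, 33.8% reached an FDR under 0.05 in replicate 2, a difference of -41.3 percentage points (95% interval -53.2 to -23.1) from peaks matched on signal, and of -40.7 points (-52.5 to -23.4) with GC content matched too. Matching on signal and GC content thus did not remove the difference. The loci were picked for their gap between these same libraries, which itself favours a low share in replicate 2, and the intervals leave that choice out. The test therefore cannot decide on depth or GC content as the whole cause. Brainstem cells in replicate 1 may be a source and cannot be told apart from others. For the Hox part the 16 genes of paralog groups 9 to 13 had a median log2 ratio of 0.17 with an interval from -0.35 to 1.65, and for the forebrain part the ratio of 2.40 (0.50 to 4.37, 13 genes) is the pattern itself and decides nothing.

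The signal of replicate 2 relative to replicate 1 rose with the GC content of shared peaks up to the decile at 59.0%, where the median log2 ratio was 0.88, and was 0.80 in the richest decile, with a Spearman's rho of 0.266 across 132322 pairs of peaks, which are not independent replicates. Promoters being rich in GC is argued against as the whole cause, since rho was 0.316 among 87571 pairs over 2000 bp from a TSS. The level of the signal is argued against as the whole cause too, since rho had a mean of 0.184 within deciles of signal, from 0.145 to 0.281. A difference in amplification or sequencing between the libraries may be the source, and only the labels of replicate 2 name instruments, so this was not tested.

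Replicate 1 had more footprints than replicate 2, with 3.19 and 2.66 per peak. If 1 signal step is 1 counted cleavage, depth in the peak may account for part of this. At the same number of steps the ratio of footprints per peak was 1.11, against 1.20 without matching. This lies above the range of 0.9 to 1.1 set beforehand for depth as the whole cause, but that range was not drawn from libraries of like depth, which the design lacks, and the interval of 1.11 to 1.12 covers the sampling of peaks alone. Depth therefore cannot be told apart from other differences between the 2 libraries.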
